A study of Mus musculus with 33 samples.

How the data were processed

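The data came from brown adipose tissue (BAT), the fat depot that burns fuel to make heat, of male mice kept at 30 °C for 14 days. NCoR1 and NCoR2 (also called SMRT) are nuclear receptor corepressors, proteins that recruit the histone deacetylase HDAC3 to chromatin and lower the transcription of nearby genes. Each was deleted in brown adipocytes with a Cre recombinase driven by the Ucp1 promoter, alone or together, and every knockout line had its own control group. RNA was sequenced from 4 NCoR1 controls, 3 NCoR1 knockouts, 4 NCoR2 controls, 4 NCoR2 knockouts, 4 NCoR1/2 controls and 4 NCoR1/2 double knockouts, 23 libraries in all. HDAC3 chromatin immunoprecipitation (ChIP-seq) used 3 control and 3 double-knockout libraries, with 2 HDAC3-knockout libraries as background, 1 IgG library and 1 input library, 10 in all. Groups and replicate numbers were taken from the sample titles; that of double knockout 1 names both genes but calls the sample a knockout, and it was kept as a double knockout. The labels do not say that the replicates came from separate animals, so the p-values measure only the spread between these samples, which may be technical.

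The RNA was not processed alike in the 3 lines. Per the labels' protocols, the NCoR1 line was made into libraries with a stranded total RNA kit and read from a single end at 75 nucleotides at a university core, while the NCoR2 and NCoR1/2 lines were read in pairs of 150 nucleotides by a commercial provider. The line and the sequencing site therefore cannot be told apart for NCoR1, and levels were compared only within a line, between knockouts and their own controls. The submitters' processing notes name kallisto, edgeR and limma for RNA without versions, Bowtie2 2.4.2, SAMtools and HOMER 4.11.1 for ChIP-seq, and the builds GRCm38 and mm10, which are the same assembly under its 2 names. Settings of these tools were not given in the sources used here.

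The authors deposited, for each RNA library, estimated counts for 119414 Ensembl transcripts with the effective length of each; such counts need not be whole, because a read that matches several transcripts is divided among them. They were rounded to whole numbers before testing. The reference used here pairs gene symbols with gene identifiers but not with transcript identifiers, so the counts could not be summed to genes, and the gene-level tests written before the data were examined were run on transcripts instead, which are counted and not named. Transcripts of one gene share reads, so their calls are not independent of each other. The authors also deposited 1 table per line holding a log2 fold change (knockout over control) for each gene they listed, with no error and no p-value. The rule by which genes entered these tables was not given in the sources used here; the smallest absolute log2 fold change was 0.53 in the NCoR1 table, 0.54 in the NCoR2 table and 0.55 in the NCoR1/2 table. All gene names and gene fold changes come from these tables, and a gene absent from one is only "not listed" there. For ChIP-seq the authors deposited 1 peak list for the controls and 1 for the double knockouts, and the score column of both deposited lists holds the value 1 for every peak, so peaks could not be ranked. How the 3 libraries of a genotype entered a list was not given in the sources used here, so peak counts have no replicate error, and the depth of the ChIP-seq libraries is unknown here.

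Transcripts were filtered with filterByExpr, scaled with TMM and tested with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, line by line, and p-values were adjusted by the Benjamini-Hochberg (BH) method with a threshold of 0.05. Differences between knockout effects, and the departure of the double knockout from the sum of the single knockouts on the log2 scale, were contrasts in 1 fit of all 6 groups. Log2 CPM (counts scaled to the library total) for principal components and for group overlaps used a prior count of 2. The estimated totals ran from 7623799 to 39795945 counts per library. Before averaging, the 253 pairs of libraries were checked for duplicates: 0 pairs were identical, the highest Spearman correlation was 0.936, and every pair within a group varied by at least 14.3 times its sampling noise.

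The sensitivity of the transcript test was tested on simulated data, made from the real means and library sizes. In them 200 transcripts with an average log2 CPM of at least 1 were changed by a known fold. Recovery among less abundant transcripts was not simulated, nor was recovery when as many change as the 8019 called in the double knockout. With the NCoR1 design 0% of the 1.5-fold, 3% of the 2-fold and 36.4% of the 4-fold changes were recovered. The NCoR2 design recovered 1.5%, 22.4% and 68.2%, and the NCoR1/2 design 6%, 32.8% and 72.7%. For the contrast of NCoR1/2 with NCoR2 these shares were 1.5%, 16.4% and 54.5%. Calls of transcripts that had not been changed numbered 0 of 26 in the NCoR1 simulation, 12 of 73 for NCoR2, 10 of 84 for NCoR1/2 and 1 of 49 for the contrast, so the share of false calls in the NCoR2 and NCoR1/2 simulations was above the threshold of 0.05. The biological coefficient of variation was 56.1% in the NCoR1 line, 43.1% in the NCoR2 line and 41.2% in the NCoR1/2 line.

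The 26 gene lists, 501 genes in all, were fixed before the data were examined: thermogenesis and brown adipocyte identity, de novo lipogenesis, triglyceride synthesis, lipolysis and lipid uptake, fatty acid oxidation, oxidative phosphorylation (nuclear and mitochondrially encoded), the tricarboxylic acid cycle, glycolysis, cholesterol synthesis, thyroid hormone and liver X receptor targets, PPAR targets, the circadian clock, the corepressor complex, stress responses, apoptosis and p53 targets, the cell cycle, inflammation, the extracellular matrix with fibroblasts, and markers of white adipocytes, macrophages, lymphocytes, endothelium, skeletal muscle, nerve and red blood cells. The list tests planned on gene-level expression could not be run. In their place, a list with at least 3 members in a table was tested for direction with a two-sided Fisher's exact test of higher against lower members set against all other genes of that table, BH adjusted over the lists of the table. This test asks whether a list leans more to 1 side than the rest of the table, and genes of a list are not independent of each other. On simulated lists drawn from the 3113 genes listed for NCoR1/2 it called 100% of 200 one-sided lists and 2% of random ones. That recovery does not hold for lists with few listed genes. Real lists with 3 listed genes, all on 1 side, had unadjusted p-values of 0.254 (higher) and 0.0943 (lower) for NCoR1 by this test. For NCoR1/2 such a list had 0.112 (lower). The counts "adjusted over the list alone" could not be made without gene-level p-values. List genes were matched to the authors' deposited tables by exact symbol. Gk, on the thermogenesis and PPAR lists, stands in the NCoR1 and NCoR1/2 tables under its other symbol, Gyk (0.59 and -1.08). It is therefore missing from the counts and tests of these lists.

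Genes were named by a rule written before the data were examined: always Ncor1, Ncor2, Hdac3 and Ucp1, then the 8 genes listed as most higher and the 8 as most lower in each table, leaving out predicted genes, and up to 4 members per list. The rule also asked for small adjusted p-values and for groups without overlap, which the tables do not give, so list members were taken by absolute log2 fold change. Ppargc1a, Prdm16, Adrb3, Csf1r, Abca1 and the proteasome genes were named as well, after their values were seen.

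Peaks were compared in GRCm38/mm10 by an overlap of at least 1 bp, and chance overlap was estimated from 100 randomly shifted lists. A gene was near a peak when the peak lay within 10 kb of the gene's span, from a RefSeq table of GRCm38.p6 that matched 98.3%, 97.5% and 98.5% of the symbols in the NCoR1, NCoR2 and NCoR1/2 tables. That table gives a start and an end for each gene without strand, exons or introns, so a peak is described as inside or beside a gene span, and the planned distance to gene starts was replaced by distance to spans. Shares carry 95% Wilson intervals, which cover counting error only. Tests used pandas 2.3.3, SciPy 1.17.1 and statsmodels 0.14.6 in Python 3.11.15.

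Alternatives fixed before the data were examined were DESeq2 1.42.0, limma 3.58.1 with voom weights, RLE scaling, no scaling factors, effective-length offsets, no filter on low counts, 1 joint fit of all groups, the replicate number as a block, and leaving out each library in turn. For control peaks they were distances of 1 kb and 50 kb, and for the peak lists a larger overlap of the peaks and centres within 500 bp, and for overlaps of calls an adjusted p under 0.01. A binomial test of the lists, tables restricted to genes changed at least 2-fold, those distances for double-knockout peaks, a gene length term and the removal of immune genes or of proteasome genes were added after seeing the data. Leaving out TMM factors moved the median log2 fold change of all transcripts by 0.128 in the NCoR2 line (from 0.009 to 0.137), by -0.094 in the NCoR1 line and by 0.077 in the NCoR1/2 line. It moved the contrast of NCoR1 with NCoR2 by -0.19 and that of NCoR1/2 with NCoR1 by 0.117. Fold changes are therefore relative to the bulk of transcripts in a library.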

Results

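RNA was sequenced from BAT of mice lacking NCoR1, NCoR2 or both in brown adipocytes, each line beside its own controls, after 14 days at 30 °C, a temperature at which mice need little heat from this tissue. The NCoR1 controls held 7623799, 18837364, 21461219 and 23172005 estimated counts, and the NCoR1 knockouts 11338294, 24980481 and 11838967. The NCoR2 controls held 14366233, 29787630, 28026747 and 33426386 and the NCoR2 knockouts 29797022, 36063769, 32750933 and 36824936. The NCoR1/2 controls held 35954184, 27813862, 31801126 and 39795945 and the double knockouts 33857836, 37913722, 33260990 and 36091536. The NCoR1 line was on average sequenced less deeply, and it was also prepared with another kit at another site. HDAC3 binding was recorded as 1 peak list for NCoR1/2 controls and 1 for double knockouts.

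The targeted genes were looked up first. Ncor1 was listed as lower in the authors' deposited table for the NCoR1 knockout, with a log2 fold change of -1.06, a 2.1-fold difference. It was not listed for the NCoR1/2 double knockout, and neither Ncor2 nor Hdac3 was listed in any of the 3 tables. A gene that is not listed has no value here, the parts of the genes that were deleted were not given in the sources used here, and BAT also holds cells that do not carry the deletion. The targeted gene could not be followed library by library, since transcripts were not paired with gene names, so the labels of single libraries rest on the titles alone.

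In the NCoR1 knockout, which asks what loss of 1 corepressor does, genes of heat production and fat use were listed as higher. Ucp1, the mitochondrial uncoupling protein that makes heat, had a log2 fold change of 3.18 (9.1-fold) in the authors' deposited table, and Acot11, Ucp3 and Otop1 had 1.10, 1.05 and 1.00. Of the 30 genes of thermogenesis and brown adipocyte identity 7 were listed as higher and 0 as lower. Fatty acid oxidation had 8 of 26 genes higher and 0 lower, with Acaa1b at 1.04, Slc25a20, the carnitine-acylcarnitine carrier, at 1.00, Ehhadh at 1.00 and Pdk4 at 0.88 in the authors' deposited table. De novo lipogenesis had 5 of 20 higher and 0 lower, led in the authors' deposited table by the desaturases Scd1 at 2.20 and Scd2 at 1.54, with the elongases Elovl5 at 0.72 and Elovl6 at 0.65. PPAR targets had 6 of 27 higher and 0 lower. As matched by symbol, direction did not pass BH adjustment for any of the 10 lists tested by Fisher's exact test, although 3 had unadjusted p-values under 0.05: fatty acid oxidation (p = 0.00902, adjusted p = 0.0872), thermogenesis (p = 0.0174, adjusted p = 0.0872) and PPAR targets (p = 0.0339, adjusted p = 0.113). The thermogenesis and PPAR counts leave out Gk, listed as Gyk at 0.59. With it thermogenesis would have the same counts as fatty acid oxidation, so whether these lists pass adjustment is not settled here.

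Other groups of the NCoR1 line held few listed genes. The clock list had 2 genes higher and 2 lower (adjusted p = 1.0 by Fisher's exact test): Arntl, which encodes the core activator BMAL1, at 2.35 and Nfil3 at 1.65, against Per1 at -0.85 and Rorc at -0.74 in the authors' deposited table. All 3 listed markers of white adipocytes were lower in the authors' deposited table, Nnat at -2.62, Ccdc80 at -0.94 and Cfd at -0.81 (p = 0.0943, adjusted p = 0.189, Fisher's exact test). By Fisher's exact test the adjusted p was 0.165 for lipogenesis, 0.215 for glycolysis (4 higher, 0 lower), 0.318 for nuclear-encoded oxidative phosphorylation and for thyroid hormone and liver X receptor targets (3 higher, 0 lower in each), and 0.66 for stress responses (1 higher, 2 lower). Except for stress responses these lists were wholly on the higher side, yet their unadjusted p-values were 0.066, 0.129 and 0.254 (Fisher's exact test). With so few listed genes no upward lean could pass, so these values do not show that a lean is absent. Lists with fewer than 3 listed genes were not tested: triglyceride synthesis, lipolysis and the tricarboxylic acid cycle had 2 higher each, p53 targets 2 lower, and inflammation and endothelium 1 lower each. Within the corepressor complex Ncor1 was lower and Tbl1xr1, a subunit of the complex, was at 1.55 in the authors' deposited table. Mitochondrially encoded subunits, cholesterol synthesis, extracellular matrix, cell cycle, and the markers of macrophages, lymphocytes, skeletal muscle, nerve and red blood cells had 0 listed genes.

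The genes of largest change in the authors' deposited table for NCoR1 were Myl6 (4.70), Stard3nl (4.66), Gfer (4.20), Rce1 (3.43), Ucp1, Cradd (3.06), BC003965 (3.04) and E2f3 (2.88) upward. Downward the authors' deposited table had Wdr19 (-3.59), Tusc3 (-3.56), Gart (-3.45), Pck2 (-3.00), Isyna1 (-2.88), Amigo2 (-2.87), Lrrn4cl (-2.76) and Nnat. It held 480 genes, 261 higher and 219 lower, of which 90 and 80 differed at least 2-fold. In the libraries themselves 11 transcripts rose and 8 fell among 43884 tested (edgeR quasi-likelihood, BH adjusted p under 0.05), and 3999 had an unadjusted p under 0.05. The number depended on the tool, with 1406 by DESeq2 and 59 by voom, and on single libraries: 6 transcripts passed without NCoR1 control 1, and 0 passed without any 1 of the other 6 libraries.

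In the NCoR2 knockout skeletal muscle markers were listed as lower. All 20 skeletal muscle markers were lower in the authors' deposited table, from -5.89 to -0.96 with a median of -4.38, and this direction differed from the rest of that table (two-sided Fisher's exact test, p = 0.00296, the 1 list with enough members). Among genes changed at least 2-fold 19 markers were lower and 0 higher (p = 0.144, Fisher's exact test). Of the 224 genes of that size 195 were lower, so no lower lean of this list could pass there. The muscle myosins Myh2 (-5.89, 59.5-fold) and Myh4 (-5.34), the skeletal actin Acta1 (-5.27), the creatine kinase Ckm (-4.92), the calcium channel Ryr1 (-4.88), Mybpc1 (-4.74), Tcap (-4.73) and Pvalb (-4.67) were the most negative in the authors' deposited table. Upward the authors' deposited table had Rps6ka5 (2.93), Chrnb2 (2.30), Pianp (2.27), Satb2 (2.18), P2ry14 (2.15), Tfap2c (2.13), Zfp821 (2.12) and Rad54l (1.94). The authors' deposited table did not list Ucp1, and the other lists had at most 1 member in it: Fitm1 (-3.27) of triglyceride synthesis, Tpi1 (-1.21) of glycolysis, Ndufa9 (-0.70) of nuclear-encoded oxidative phosphorylation, and Fabp3 (-0.64), shared by lipid uptake and PPAR targets. The remaining 20 lists had 0 listed genes.

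The transcripts of lowest fold change in the NCoR2 line, which were not paired with genes, differed between libraries of the same genotype. The 230 transcripts with a log2 fold change of -2 or lower and an average log2 CPM of at least 1 averaged 109.32, 17.5, 95.28 and 23.39 CPM in NCoR2 controls 1 to 4 and 2.43, 31, 4.88 and 0.79 CPM in knockouts 1 to 4. Group means were 61.37 ± 47.67 CPM (SD, n = 4) and 9.78 ± 14.25 CPM (SD, n = 4). These transcripts were chosen by their fold change between the same groups, so no test of the means is given. By edgeR quasi-likelihood 0 of the 230 passed BH adjustment, and 119 had an unadjusted p under 0.05. In the whole line 2 transcripts rose and 1 fell among 43531 (BH adjusted p under 0.05), 2747 had an unadjusted p under 0.05, DESeq2 called 66 upward and 216 downward, and voom called 2. Without NCoR2 knockout 4, 2 transcripts passed, and 0 passed without any 1 of the other 7 libraries. The authors' deposited table for NCoR2 held 316 genes, 81 higher and 235 lower.

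**Figure D1:**
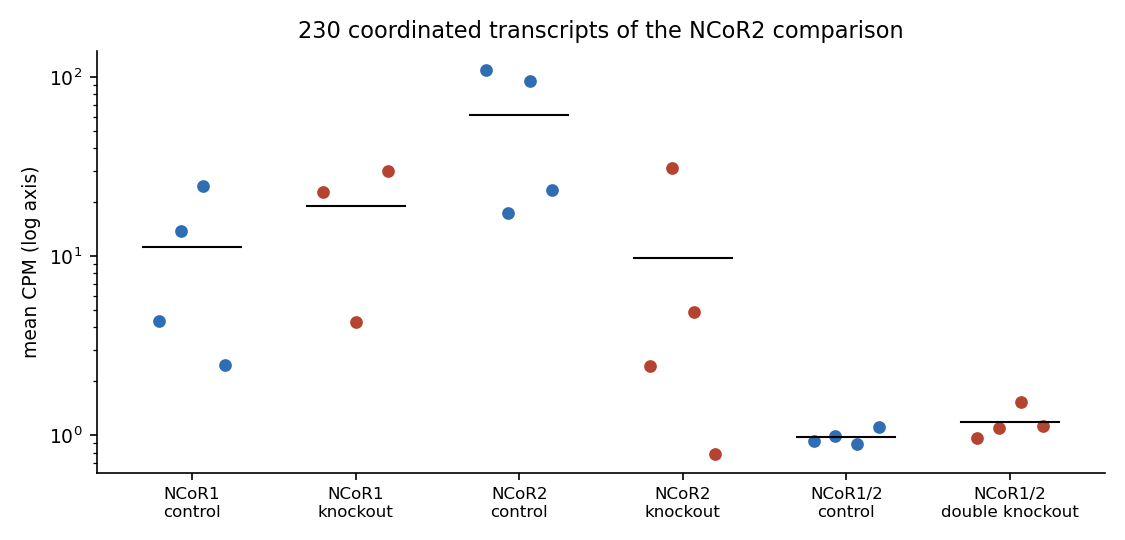
Mean CPM (vertical axis, log scale) of the 230 transcripts with a log2 fold change of -2 or lower in the NCoR2 line, with a point for each of the 23 RNA libraries, blue for controls and red for knockouts, and a line at each group's mean. NCoR2 controls 1 and 3 stand at 109.32 and 95.28 CPM, NCoR2 knockout 2 at 31 CPM above controls 2 and 4, and the NCoR1/2 libraries lie between 0.89 and 1.53 CPM.

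In the double knockout, which asks what happens when both corepressors are lost, 8019 transcripts changed. Genes of brown adipocyte identity were split: 4 of 30 were listed as higher and 13 as lower, without counting Gk, listed as Gyk at -1.08. Elovl3, a fatty acid elongase, had a log2 fold change of 5.33 (40.2-fold) in the authors' deposited table, Ucp3 had 2.83, the adrenergic receptor gene Adrb3 1.50 and Ucp1 1.01 (2-fold). On the lower side the authors' deposited table had Ntrk3 at -3.92, S100b at -3.65, and the transcriptional regulators of mitochondria and brown fat Ppargc1a at -0.90 and Prdm16 at -0.72. This lean toward lower values did not pass adjustment (p = 0.0262, adjusted p = 0.0722, Fisher's exact test). Mitochondrially encoded subunits of the respiratory chain did pass it, with 7 of 13 lower and 0 higher (p = 0.00596, adjusted p = 0.0488), among them mt-Co1 (-0.94), mt-Nd4l (-0.92), mt-Nd4 (-0.79) and mt-Nd2 (-0.78) in the authors' deposited table; the call was lost with a binomial test, and 0 of the 7 genes changed at least 2-fold. The tricarboxylic acid cycle had 7 of 19 lower and 1 higher (adjusted p = 0.0722, Fisher's exact test), with Idh2 at -1.53, Pdha1 at -1.03 and Ogdh at -0.83 in the authors' deposited table and pyruvate carboxylase, Pcx, on the other side at 2.62. Nuclear-encoded oxidative phosphorylation had 3 of 47 lower and 0 higher (adjusted p = 0.175, Fisher's exact test), too few listed genes for any lean to pass. Macrophage markers were higher in the same table (20 of 22), and a change in the makeup of the tissue was not set apart from these lower values.

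Among the lipid genes listed for the double knockout more were higher than lower in each list given here, but most of these lists did not pass adjustment. Targets of thyroid hormone and liver X receptors, nuclear receptors that bind NCoR proteins, had 11 of 18 higher and 1 lower (p = 0.00665, adjusted p = 0.0488, Fisher's exact test), with the lipid carrier Apoe at 2.77, Scd1 at 2.34, Lpcat3 at 2.17 and Hr at 2.09 in the authors' deposited table; 5 of the 18 genes are also on the lipogenesis list, and this call too was lost with a binomial test and, with 10 higher and 0 lower, among genes changed at least 2-fold (adjusted p = 0.0573, Fisher's exact test). Macrophages also express some of these genes, such as Apoe, and macrophage markers were higher in the same table (20 of 22, median log2 fold change 2.14 in the authors' deposited table). De novo lipogenesis had 11 of 20 higher and 2 lower, led by Scd2 (2.89), Scd1 and Me1 (1.81) against Mlxipl, which encodes the glucose sensor ChREBP, at -1.80 in the authors' deposited table. Triglyceride synthesis had 9 of 19 higher and 1 lower, with the lipid droplet coat gene Plin2 at 3.04 and Agpat2 at 2.81 in the authors' deposited table. Neither of these lists passed adjustment (adjusted p = 0.0722 for each, Fisher's exact test), nor did PPAR targets with 10 of 27 higher and 2 lower (adjusted p = 0.0795), lipolysis and lipid uptake with 7 of 18 higher and 1 lower (adjusted p = 0.121), or fatty acid oxidation with 6 of 26 higher and 3 lower (adjusted p = 0.623). Examples from the authors' deposited table were the fatty acid binding protein genes Fabp5 (3.29) and Fabp4 (1.52), the peroxisomal enzymes Ehhadh (4.58) and Acox1 (1.51), Acot1 (4.03), and Ppara, which encodes the receptor PPARα, at -2.25.

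Markers of macrophages formed the most one-sided list. Of 22 markers 20 were higher and 0 lower, with a median log2 fold change of 2.14 in the authors' deposited table (p = 2.28e-06, adjusted p = 5.02e-05, Fisher's exact test). Gpnmb (3.86, 14.6-fold) and Trem2 (3.57, 11.9-fold), both genes of lipid-laden macrophages, Lgals3 (2.87) and the receptor gene Csf1r (2.07) were among them in the authors' deposited table. Lymphocyte markers, the extracellular matrix and the cell cycle each had 6 higher and 0 lower (of 18, 24 and 18 genes, adjusted p = 0.0722 for each, Fisher's exact test), including Ighm at 5.63, Mmp12, a macrophage elastase, at 3.38, and Mki67 at 1.01 in the authors' deposited table. Inflammation had 5 of 22 higher and 0 lower (p = 0.0632, adjusted p = 0.116, Fisher's exact test), with Usp18 at 3.49 and Lcn2 at 2.38 in the authors' deposited table. With so few listed genes no upward lean of that list could pass. With a binomial test the macrophage list alone passed of the 3 lists called in this table, and among genes changed at least 2-fold it passed with 18 higher and 0 lower (adjusted p = 0.00171, Fisher's exact test). Endothelial (14 genes), red blood cell (8) and skeletal muscle (20) markers had 0 listed genes, and nerve markers 2 lower of 14.

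The remaining lists showed no lean that passed Fisher's exact test in the double knockout. The clock list had 7 of 20 higher and 2 lower (adjusted p = 0.267), with Npas2 at 5.33 (40.3-fold) and Arntl at 4.57, partners in the activating arm of the clock, and Nr1d1 at 1.37 in the authors' deposited table. The corepressor complex had 3 higher and 1 lower (adjusted p = 0.725), with Nrip1 at 1.65, Tbl1xr1 at 1.55 and Sin3a at -0.67 in the authors' deposited table. Glycolysis had 2 higher and 4 lower (adjusted p = 0.589), cholesterol synthesis 3 and 3 (1.0), stress responses 5 and 5 (1.0), white adipocyte markers 3 and 2 (1.0), and p53 targets 5 and 2 (0.589). White adipocyte genes went both ways in the authors' deposited table, with Sncg at 4.24 and Nnat at -2.25. The genes of largest change in the authors' deposited table were Snai3 (6.42), Ighm, Slc25a34 (5.51), Ankrd63 (5.44), Rasef (5.40), Npas2, Elovl3 and Sypl2 (5.16) upward and Kng2 (-6.76), Lgr6 (-6.18), Sorcs2 (-6.17), Rnf182 (-5.22), Rab17 (-5.07), Lctl (-4.76), Txlnb (-4.74) and Magel2 (-4.47) downward.

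**Figure D2:**
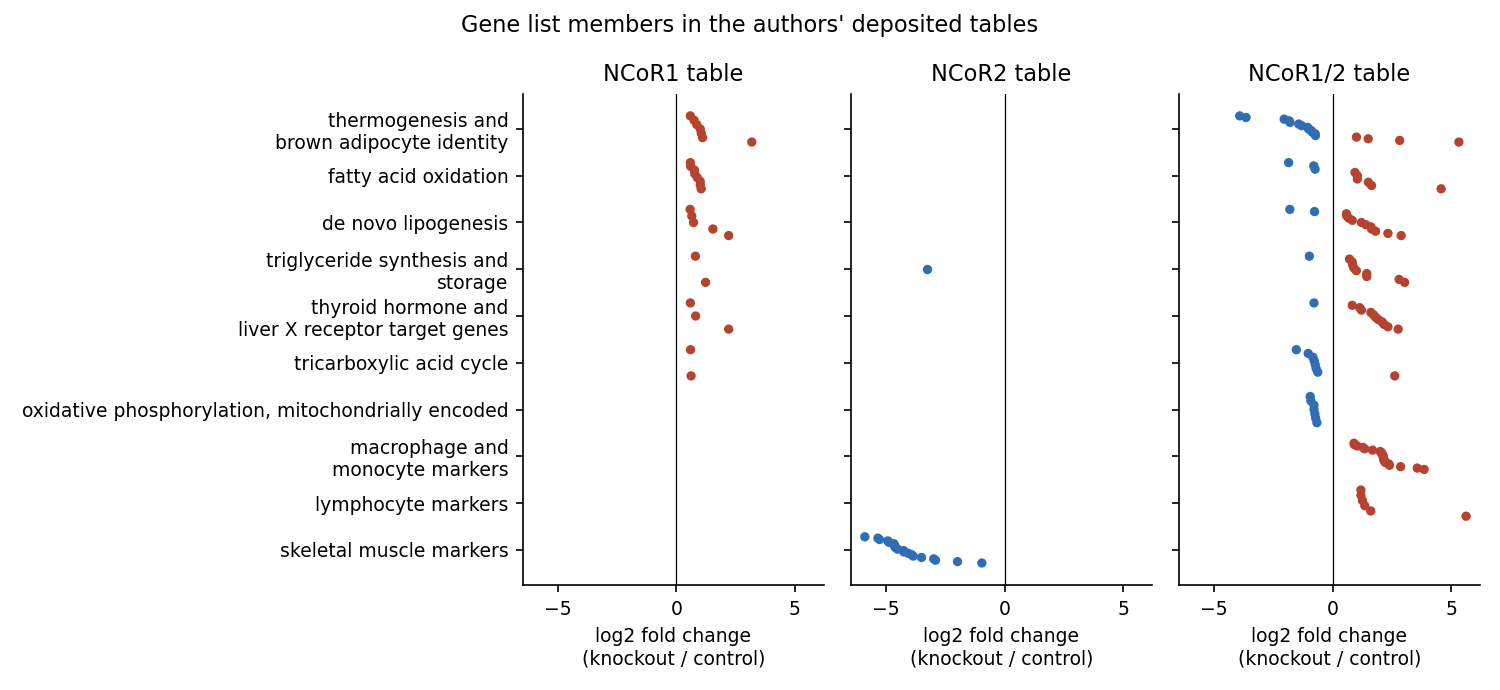
Log2 fold change of knockout over control (horizontal axis) of each gene of 10 of the fixed lists (vertical axis) that the authors' deposited tables hold, 1 point per gene, red for higher and blue for lower, with 1 panel for each of the 3 lines. All 20 skeletal muscle markers lie left of 0 in the NCoR2 panel, and 20 of 22 macrophage markers lie right of 0 in the NCoR1/2 panel.

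In the libraries 4270 transcripts rose and 3749 fell in the double knockout, 18.42% of the 43532 tested (edgeR quasi-likelihood, BH adjusted p under 0.05), with a median absolute log2 fold change of 0.96; 3786 of them changed more than 2-fold and 1151 more than 4-fold. The double-knockout libraries separated from their controls on the first principal component, at 85.4 to 109.6 against -106.8 to -88.7. The 10 most abundant transcripts took 26.82 ± 1.63% of the counts (SD, n = 4) in double knockouts and 34.73 ± 2.33% (SD, n = 4) in controls (two-sided exact permutation test, p = 0.0286, the smallest this design allows). The authors' deposited table held 3113 genes, 1614 higher and 1499 lower, and 908 and 623 of these differed at least 2-fold.

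**Figure D3:**
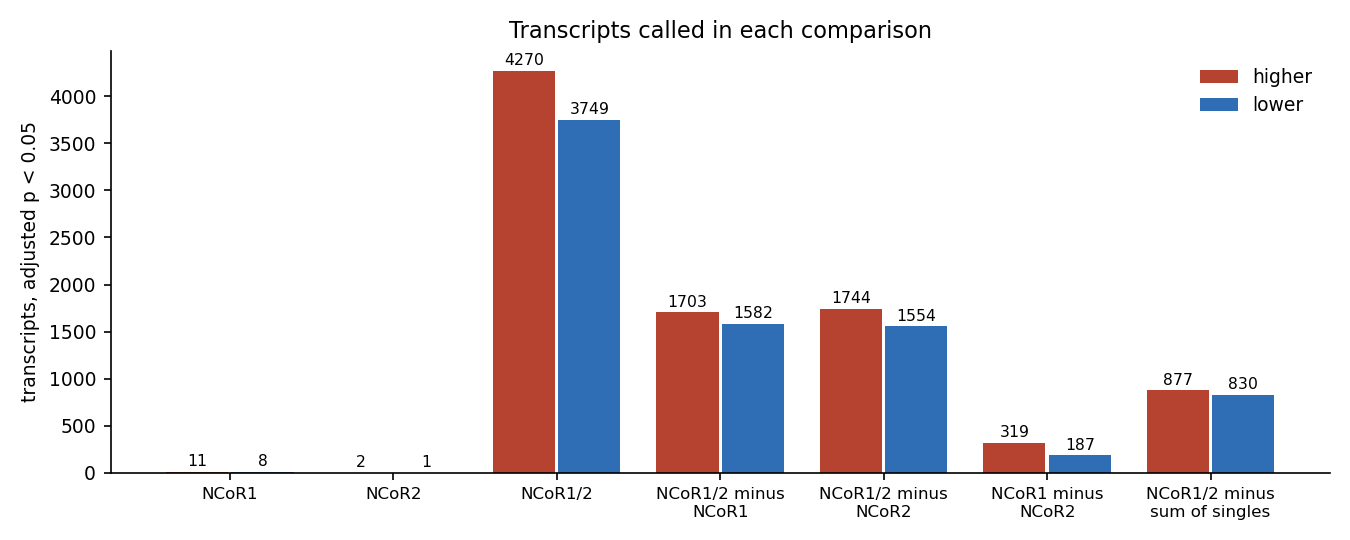
Number of transcripts (vertical axis) with a BH adjusted p under 0.05 by the edgeR quasi-likelihood test, higher in red and lower in blue, for each knockout against its controls and for the differences between knockout effects. The NCoR1/2 bars reach 4270 and 3749, against 11 and 8 for NCoR1 and 2 and 1 for NCoR2.

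Whether the knockouts differ in effect was tested as the difference itself. The fit of all groups shares 1 estimate of spread, while the coefficient of variation was 56.1% in the NCoR1 line, 43.1% in NCoR2 and 41.2% in NCoR1/2. In that fit the NCoR1 knockout alone gave 975 transcripts, against 19 in its own fit. Counts of contrasts that involve NCoR1 may therefore be too high. Transcripts whose effect differed between the double and the NCoR1 knockout numbered 3285 of 62103, 1703 higher and 1582 lower in the double knockout (edgeR quasi-likelihood, BH adjusted p under 0.05); without TMM factors the split was 2095 to 1230. Between the double and the NCoR2 knockout 3298 differed, 1744 higher and 1554 lower, and without TMM factors 1337 and 1797. Between NCoR1 and NCoR2 506 differed, 319 higher and 187 lower in NCoR1, a split that went to 135 and 319 without TMM factors and to 551 and 199 with RLE factors. That count was 303 without NCoR2 knockout 3, 325 without NCoR2 knockout 4 and 802 without NCoR1 control 4. The double knockout departed from the sum of the single knockouts, on the log2 scale, for 1707 transcripts, 877 above and 830 below. A drawn split that kept the NCoR1/2 groups and regrouped only the single-knockout libraries gave 1775, while splits that moved NCoR1/2 libraries gave at most 47. The count thus did not need the real single-knockout groups, and chance was not excluded for their part in it. Of the gene lists compared between the NCoR1 and NCoR1/2 tables, 10 in all, the listed genes of thermogenesis and brown adipocyte identity leaned to different sides. They were 7 higher and 0 lower against 4 and 13 (two-sided Fisher's exact test, p = 0.000953, adjusted p = 0.00953). The test takes the tables as independent, and most of these genes were not in both. Of those in both, Ucp1 and Ucp3 were higher in each, and Acot11 and Ppargc1a had opposite directions. So had Gk, which both tables list as Gyk and which these counts leave out. The difference thus comes mostly from which genes each table listed.

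The single and double knockouts shared part of their listed genes. Of the 480 NCoR1 genes, 224 (46.7%) were also in the NCoR1/2 table, 102 higher and 86 lower in both, so that 83.9% had the same direction (two-sided Fisher's exact test, p = 5.69e-26). Across these genes, which are not independent replicates, Pearson's r was 0.61 and Spearman's rho 0.66, and the change was larger in the double knockout for 131 of the 188 genes of equal direction. The p-value above, like the others for shared genes here, takes genes as independent of each other. Over transcripts called in the double knockout r was 0.2, and 3 of the 35 splits of the NCoR1 libraries, the real one included, gave as large a correlation. Scd1 stood at 2.20 and 2.34, Arntl at 2.35 and 4.57, Ehhadh at 1.00 and 4.58, and Tbl1xr1 at 1.55 and 1.55 in the authors' deposited tables for NCoR1 and NCoR1/2. Opposite directions were given to 36 genes, among them Ppargc1a (0.86 and -0.90), Acot11 (1.10 and -1.01), Lgr6 (1.25 and -6.18), Lrrn4cl (-2.76 and 2.43) and Ccdc80 (-0.94 and 2.16) in the authors' deposited tables. The NCoR2 and NCoR1/2 tables shared 65 genes, 67.7% of them with the same direction (p = 0.00632, Fisher's exact test), but the share was 61.5% of the 26 genes that differed at least 2-fold in both (p = 0.216), and Pearson's r across genes was 0.03. The NCoR1 and NCoR2 tables shared 11 genes, 4 in the same direction (p = 1.0, Fisher's exact test). At the level of transcripts, 6 of those that rose in the NCoR1 knockout also rose in the double knockout, against 1.08 for independent lists (p = 0.000225, Fisher's exact test), and 2 fell in both against 0.6 (p = 0.115). The NCoR2 and double knockouts shared 1 transcript, and NCoR1 and NCoR2 shared 0 by edgeR quasi-likelihood or voom and 48 by DESeq2, of which 9 had the same direction, with 3999 and 2747 transcripts at an unadjusted p under 0.05.

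HDAC3 binding in the double knockout was asked with the peak lists. The control list held 6406 peaks and the double-knockout list 3349, 1.91-fold fewer, and 544 peaks overlapped, 8.5% of the control list and 16.2% of the double-knockout list. Randomly shifted lists overlapped at a median of 4 and at most 11 peaks. Every control peak was 233 bp wide and every double-knockout peak 259 bp. With 1 list per genotype the difference in number has no replicate error, and it depends on depth and enrichment, which are unknown here.

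Several named genes of brown fat lay beside control peaks that the double-knockout list lacked, as it lacked 5862 of all 6406 control peaks. Ucp1 (chromosome 8, 83290348 to 83298456 in GRCm38/mm10) had 2 control peaks within 10 kb, the first at 83284431 to 83284663, and 0 in the double knockout. Ppargc1a (chromosome 5, 51454249 to 52115853) had 6 control peaks, the first at 51585093 to 51585325 inside the gene span; none of these was kept, and 2 double-knockout peaks lay elsewhere near the gene. Ntrk3 (chromosome 7, 78179986 to 78581034) had 7 control peaks and 0 in the double knockout, and Idh2 (chromosome 7, 80094845 to 80118608) had 2 and 0. Among genes listed as higher, Npas2 (chromosome 1, 39193702 to 39363240) had 5 control peaks, of which 1 was kept, Abca1 (chromosome 4, 53030789 to 53159988) had 3 and Ehhadh (chromosome 16, 21761285 to 21787834) had 1 inside its span. Scd1 (chromosome 19, 44394450 to 44407709) had 1 at 44416407 to 44416639, 8813 bp from the gene, while Elovl3 (chromosome 19, 46131897 to 46135694) had 0, the nearest lying 27802 bp away. By list, a control peak lay near 10 of the 13 lower and 2 of the 4 higher genes of brown adipocyte identity, 5 of 11 higher lipogenesis genes, 4 of 11 higher thyroid hormone and liver X receptor targets, 3 of 7 higher clock genes and 1 of 20 higher macrophage markers, Csf1r. Over the whole table a control peak lay near 30.4% of lower and 18.5% of higher genes, and gene length was not taken into account for the lists.

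Genes listed as lower in the double knockout lay near control HDAC3 peaks more often than genes listed as higher. A control peak lay within 10 kb of 433 of 1423 lower genes (30.4%, 95% Wilson interval 28.1 to 32.9), of 294 of 1586 higher genes (18.5%, 16.7 to 20.5) and of 2350 of 18878 genes not listed (12.4%). The odds ratio of higher against lower was 0.52 (two-sided Fisher's exact test, p = 3.49e-14), and each group exceeded the genes not listed (p = 3.72e-11 for higher and 4.15e-65 for lower, Fisher's exact test). The share of genes listed as lower went from 5.3% of 18810 genes with 0 control peaks to 11.3% of 2263 with 1, 18.9% of 535 with 2 and 27.2% of 279 with 3 or more, while the share listed as higher was 6.9%, 9.3%, 10.7% and 9.3%. The genes not listed are all other protein-coding genes of the reference, whether or not BAT expresses them. Expression was therefore not set apart from the excess over these genes or from the trend with peak number. Lower genes were also longer, with a median span of 29581 bp against 18240 bp. Double-knockout peaks lay near 13.0% of higher and 11.0% of lower genes (odds ratio 1.2, p = 0.104, Fisher's exact test); within 50 kb, a distance added for this list after seeing the data, the lean toward higher genes passed the test (odds ratio 1.25, p = 0.0106, Fisher's exact test). In the NCoR1 knockout control peaks lay near 29.3% of higher and 31.9% of lower genes (p = 0.609, Fisher's exact test), and in the NCoR2 knockout near 15.8% and 23.5% (p = 0.197).

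**Figure D4:**
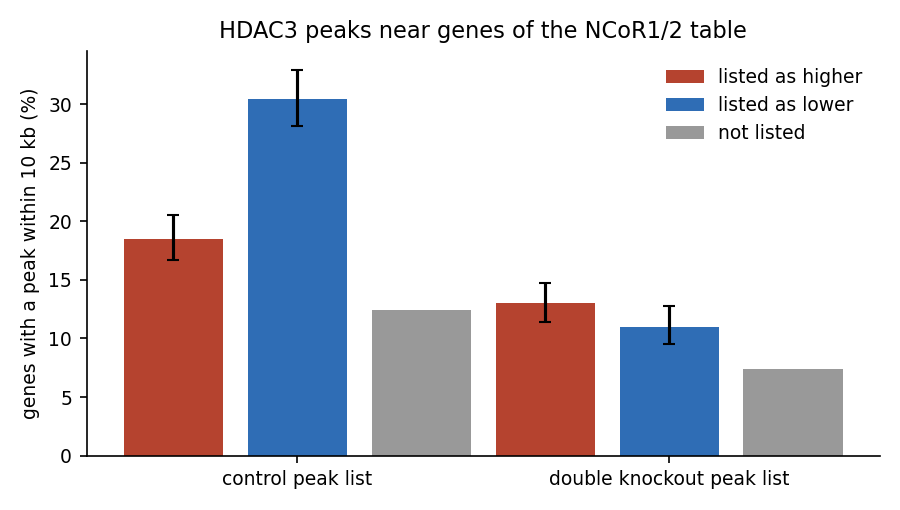
Percent of genes with an HDAC3 peak within 10 kb of the gene span (vertical axis) among genes listed as higher, lower or not listed in the double knockout, for control and double-knockout peak lists, with 95% Wilson intervals on the bars of listed genes. Control peaks lie near 18.5% of higher and 30.4% of lower genes, and double-knockout peaks near 13.0% and 11.0%.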

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

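The share of the coordinated transcripts with their highest value in 1 control library was set as a test before that value was seen; the contrasts between knockout effects were planned; the other tests in this part were chosen after the results were seen.

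In the NCoR2 line the authors' deposited table gave the skeletal muscle markers as lower, and over the 230 transcripts with a log2 fold change of -2 or lower NCoR2 knockout 2 stood apart, with a mean of 31 CPM against 0.79 to 4.88 CPM in the other knockouts. Muscle tissue carried along in 1 or 2 of the NCoR2 control samples predicts that most of these transcripts peak in the same control library, and 73.5% did so in control 1, against 41.3% for the 264 transcripts chosen alike in the NCoR1/2 line, and in the NCoR1 line the 230 also varied within genotypes, from 2.46 to 24.6 CPM in controls and 4.26 to 29.7 CPM in knockouts. A loss in each knockout predicts knockouts below all controls, which held for 9.1% of the transcripts, a share with no valid chance value because they were chosen for low knockout values, and 81.3% were higher in knockout 2 than in control 2. Muscle in some control samples may be a source of the muscle genes in the table, but it cannot be told apart from an effect of NCoR2 loss, because the 230 transcripts were not paired with genes and were not shown to be muscle transcripts. With the mean level of these transcripts as a term in the model 0 transcripts passed, and without controls 1 and 3 and knockout 2, 1 passed, by edgeR quasi-likelihood with BH adjustment, both settings chosen after seeing the data.

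Other single libraries stood apart from their group. NCoR1 control 1, the library with the fewest counts (7623799), had 30380 transcripts with at least 10 counts against 43260 to 44763 in the other NCoR1 controls, and its score on the first principal component was -263.6 against 37.6 to 43.3. NCoR2 control 1, with 14366233 counts, had 33758 such transcripts against 41074 to 42110. Chance marks about 1 in 20 combinations of a group and a quantity in this way, so 1.2 of the 25 tested were expected and 4 were found; 2 of the 4 are NCoR1 control 1.

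The size of the effects differed between the lines. The double knockout differed from the NCoR1 knockout in 3285 transcripts and from the NCoR2 knockout in 3298, and the single knockouts differed from each other in 506 (edgeR quasi-likelihood, BH adjusted p under 0.05). The departure from the sum of the single knockouts covered 1707 transcripts, but a split that regrouped only the single-knockout libraries gave 1775. Chance was therefore not excluded for the part of the single-knockout groups in that count. Counts that involve NCoR1 may be too high, because the fit shares 1 estimate of spread over the lines. In the authors' deposited tables the listed genes of thermogenesis and brown adipocyte identity leaned to different sides in the NCoR1 and the double knockout (adjusted p = 0.00953, Fisher's exact test). Most of these genes were not in both tables, so the difference comes mostly from which genes each table listed. Each line also has its own controls, the NCoR1 libraries were sequenced at another site and from a single end, and no biological explanation of these differences was tested beyond the genotypes.

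Other groupings of the same libraries were run to see whether chance could give as many calls. For the NCoR1 knockout 1 of the 35 splits, the real one, gave its 19 transcripts, and the highest other gave 1. For NCoR2 it was 1 of 35, with 3 against 1, and for NCoR1/2 1 of 35, with 8019 against 1. These shares are under 0.05 and are the smallest that 35 splits allow. The 19 and 3 calls of the single knockouts became 0 with the replicate block. Without any 1 library they became 0 to 6 and 0 to 2, so chance is not called excluded for the single knockouts. Among 30 drawn splits 1, the real one, gave as many calls for the double knockout against NCoR1 (3285, highest other 3271), for the double knockout against NCoR2 (3298 against 2598) and for NCoR1 against NCoR2 (506 against 95). For the departure from the sum 2 of the 30 splits gave as many, with 1707 in the real one and 1775 in the other, so chance was not excluded there. In all 4 contrasts the highest other count came from the 1 drawn split that kept the NCoR1/2 libraries in their real groups; splits that moved those libraries gave at most 95, 3, 89 and 47. For the 3 contrasts that include the double knockout, that points to the NCoR1/2 libraries as a structure behind many of the calls. The NCoR1 against NCoR2 count fell from 506 to 95 in that split, where only the single-knockout libraries were regrouped.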

How the results depend on the processing

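Of 197 values recomputed under other settings for 20 results, 152 stayed the same and 45 did not. A count stayed the same when its total was within 1.5 times the main one, whichever way its calls split. Shares and odds ratios stayed the same when they kept their direction and their side of the threshold. The total for NCoR1 against NCoR2 without TMM factors was thus the same, although its split reversed (135 higher and 319 lower, against 319 and 187). Of the settings 180 were planned and 17 were chosen after seeing the data. The double-knockout count of 8019 transcripts ran from 6246 with the replicate block to 10089 with DESeq2, and from 6348 to 6847 without any 1 library. Its HDAC3 results moved little: 544 shared peaks became 502 or 557 under the other overlap rules, and the odds ratio of 0.52 near control peaks ran from 0.35 to 0.68; that of 1.2 near double-knockout peaks was 1.25 within 50 kb, a distance added after seeing the data, where it passed Fisher's exact test. NCoR1 gave 19 transcripts by edgeR, 1406 with DESeq2, 975 in the fit of all 23 libraries, 59 with limma-voom, 10 with no filter on low counts, 0 with the replicate block, and 0 to 6 without any 1 library (0 without any but control 1). NCoR2 gave 3, 282 with DESeq2, 1 in the fit of all libraries, 0 with the replicate block, 0 to 2 without any 1 library (0 without any but knockout 4), 0 with a term for the coordinated transcripts and 1 without controls 1 and 3 and knockout 2. With DESeq2 the contrasts rose to 5553 (double against NCoR1), 5762 (double against NCoR2), 2265 (NCoR1 against NCoR2) and 3688 (departure from the sum). The NCoR1 against NCoR2 count of 506 also went to 276 with no filter, to 826 with the replicate block, and from 303 without NCoR2 knockout 3 (325 without NCoR2 knockout 4) to 802 without NCoR1 control 4. Transcripts called in both of 2 knockouts in the same direction went from 0 to 9 (NCoR1 and NCoR2), from 8 to 543 (NCoR1 and NCoR1/2) and from 1 to 75 (NCoR2 and NCoR1/2) with DESeq2, to 36 for NCoR1 and NCoR1/2 with limma-voom, and to 0 for both pairs with NCoR1/2 at an adjusted p under 0.01. Among genes changed at least 2-fold 0 lists passed in the NCoR2 table and 1 in the NCoR1/2 table, 1 passed there with a binomial test, and the share of NCoR2 and NCoR1/2 genes of equal direction was 61.5% and no longer passed Fisher's exact test (p = 0.216). In the NCoR2 table all 19 muscle markers of that size were lower, as were 195 of its 224 genes of that size, so no lower lean of that list could pass. The 115 Reactome pathways became 26 without proteasome subunit genes. Fewer libraries or fewer listed genes lower the power by construction; for the other settings the cause was not tested. The replicate numbers were not treated as pairs: libraries of equal number correlated at -0.064 to 0.087 in their deviations from the group means; with the block the other contrasts gave 3039, 2643 and 1747 transcripts, of which 2369, 2355 and 1212 were also called without it. Recovery of simulated 4-fold changes was lowest in the NCoR1 line, at 36.4%; this line has lower depth, more variation and 3 knockouts, and depth alone was not varied. Not run were the tests on gene sums, on list expression (camera and fry, with their blocked, left-out and RLE versions) and on named genes, which need transcripts paired with genes, the peaks of higher score, since all scores were 1, and a background matched on expression.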

Other observations

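All tests in this part were chosen after the results were seen.

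Genes of the proteasome, the complex that degrades tagged proteins, were on the higher side in the double knockout. Of 39 genes encoding its core and regulatory subunits 18 were in the authors' deposited table for NCoR1/2, and all 18 were higher, with log2 fold changes from 0.62 to 1.20 and a median of 0.79 (two-sided Fisher's exact test, p = 8.84e-06). Psmb5, a catalytic subunit, stood at 1.20, the immunoproteasome subunit gene Psmb8 at 1.16, Psma1 at 1.08 and Psma5 at 1.05 in the authors' deposited table. The NCoR1 table listed 0 of the 39 genes and that for NCoR2 listed 1. Macrophage markers were also higher in the NCoR1/2 table (20 of 22), and the cell type behind the proteasome values was not tested. A control HDAC3 peak lay near 1 of the 18.

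Among Reactome pathways 288 could be tested for direction in the NCoR1/2 table, and 115 passed after BH adjustment (Fisher's exact test), 113 of them leaning to higher genes and 2 to lower ones. The innate immune system had 116 higher and 25 lower genes (adjusted p = 5.37e-12), interferon gamma signalling 21 and 2 (adjusted p = 0.000356) and extracellular matrix organisation 40 and 15 (adjusted p = 0.00534). The 2 on the other side were pyruvate metabolism with the citric acid cycle, with 2 higher and 13 lower (adjusted p = 0.00939), and the citric acid cycle with respiratory electron transport, with 6 and 17 (adjusted p = 0.0482). Pathways share genes, and many of those called hold the same proteasome genes: degradation of DVL, stabilization of p53 and Hedgehog ligand biogenesis each had 20 higher and 0 lower. Without the proteasome subunit genes 26 of 228 pathways passed, 25 leaning to higher genes and 1 to lower ones, the innate immune system among them with 98 and 25 (adjusted p = 1.57e-08, Fisher's exact test).

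The rise of macrophage markers in the double-knockout table was weighed against a change in the makeup of the tissue. Fewer brown adipocytes would raise the markers of the other cell types alike, and macrophage markers were listed as higher far more often than endothelial ones (20 of 22 against 0 of 14, p = 3.16e-08, Fisher's exact test), and more often than lymphocyte (6 of 18, p = 0.000207) and fibroblast or matrix genes (6 of 24, p = 6.08e-06), which did include higher members. Macrophage markers were thus listed more often than those of the other types. A marker that is not listed has no value here, the rule of entry is unknown, and the smallest absolute log2 fold change listed was 0.55. The comparison therefore cannot show that the other types did not rise, and fewer brown adipocytes stay open as a source. Release of macrophage genes from HDAC3 sites would place control peaks near them, but 1 of 20 had a peak within 10 kb against 18.7% of the other higher genes, a difference that did not pass Fisher's exact test (p = 0.151) and leaves this open. More macrophages, or a changed state of those present, may lie behind these values, and no count of cells was used here to tell these apart.

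Genes listed as lower lay near control HDAC3 peaks more often than genes listed as higher. Gene length alone is argued against, since with length as a term the odds ratio of higher against lower was 0.68 (95% interval 0.57 to 0.82, p = 3.71e-05, logistic model over genes, n = 3009). Higher immune genes that brown adipocytes might not use leave part of it open: outside the immune gene sets the odds ratio was 0.57 (p = 2.35e-10, Fisher's exact test), but these sets do not hold every immune gene. Loss of HDAC3 from its sites as the source of the lower levels predicts no such lean at the peaks kept in the double knockout. There the odds ratio was 0.48 (p = 0.00545, Fisher's exact test) on 1.5% and 3.0% of the genes, against 0.52 at the peaks that were not kept. Within 1 kb it was 0.46 (p = 0.00955, Fisher's exact test) at kept peaks against 0.51. Within 50 kb it was 0.83 (p = 0.288, Fisher's exact test) at kept peaks against 0.66 (p = 2.62e-08). The distances give different answers, so this stays open. Binding near genes that are active in brown adipocytes, which fall when the cells change, was not tested, because levels of named genes in the libraries were not used here.

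In the double knockout 61.3% of its called transcripts had the same sign in the NCoR1 knockout and 56.3% in the NCoR2 knockout. Correlations of the fold changes across these transcripts were 0.2 and 0.19. Of the 35 splits of the single-knockout libraries, the real one included, 3 and 8 gave correlations as large, with 0.24 and 0.3 as the highest of the other splits.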
